A study of Mus musculus with 2 samples.

How the data were processed

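Mouse retina from 1 library per light condition was profiled with droplet single-cell RNA sequencing (10x Genomics, 3′ chemistry v3.1 or v4, per the labels' protocols, which do not settle which). Tissue was minced, digested at body temperature and strained before loading, per the labels' protocols. The deposited values are raw UMI counts per gene and barcode, made by the authors with Cell Ranger 9.0.0 per the file headers, against mm10 per the submitters' processing notes. Those notes also name Seurat and edgeR without versions. The deposited matrices held 32285 genes, and UMI counts were used as deposited.

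Barcodes with at least 300 genes and at most 20% mitochondrial UMIs were kept, which left 16095 of 16106 short-wavelength and 5695 of 5707 white-light barcodes. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold marked 14.5% of short-wavelength barcodes, which were removed. In the white-light library it marked 0.0176%, under the minimum of 0.5%, so the highest scores were removed at 0.8% per 1000 barcodes, which came to 4.83%. The libraries were thus not treated by the same rule, and results with doublets kept are among the alternatives.

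Both libraries were scaled to 10000 UMIs per cell and log-transformed. They were clustered together without integration on 2000 variable genes, 30 principal components and 15 neighbours by the Leiden method at resolution 1 (igraph 0.11.9, scikit-learn 1.9.0, Python 3.11.15). Clusters were named from marker genes of 21 cell types, fixed before the data were examined. The naming rule was set after the data were seen. It asks for a mean scaled marker level of at least 0.5 and for 3 detected markers at 50 CPM. A cluster stays unnamed where its 10 leading genes hold more markers of another type, which left most of the unnamed clusters so, or where a non-rod cluster has a rod score of 0.7 or more. It also stays unnamed where another type scores within 0.15 on at least 3 detected markers that it does not share with the best type. Over all markers, shared ones included, the Müller glia-like cluster scored 0.988 as astrocyte, and the glycinergic amacrine-like cluster 0.614 against 0.564 as GABAergic amacrine, so these names are less sure. Unnamed clusters of at least 60 cells were divided once more. The rod limit kept droplets with haemoglobin and rod RNA out of the erythrocyte class: 3 short-wavelength droplets (0.0218%) and 60 white-light droplets (1.11%). Cell names are rebuilt from markers, and no deposited annotation was used.

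UMIs were summed per class and library. Classes with at least 50 cells in both libraries, rods and cones, were compared by plan. Rod bipolar-like, Müller glia-like and microglia or macrophage-like cells, with at least 20 cells in both, were added after their numbers were seen. Ratios are ratios of CPM with the exact conditional binomial interval of 2 Poisson counts, and log2 ratios add 5 CPM to each value. Shares carry exact Clopper-Pearson intervals. With 1 library per group, no p-value was computed, since cells are not replicates. The rule for named genes was fixed in advance: at least 50 UMIs and 20 CPM in a library, at least 10 cells, and an interval wholly beyond 1.5-fold, ranked by the nearer bound, with the first 5 in each direction named. Mitochondrial, ribosomal, haemoglobin, sex-linked and predicted genes were left out of the ranking, as were genes more abundant in rods for other classes.

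Lists of genes, 31 in all and fixed in advance, were summarised by the median log2 ratio of members with at least 10 UMIs. Each median was placed among 10000 random lists of the same size, matched on expression in 20 bins, and said to stand apart in the outer 2.5% on either side; up to 4 members with at least 50 UMIs were named. Gene positions come from the GENCODE annotation of mm10, matched by gene identifier for 208 of 208 named genes.

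The steps were tested on simulated data, drawn as Poisson counts from the pooled profile of both libraries. The simulation held no variation between libraries or cells, so its rates cover counting error only. In rods, 50 of 50 genes raised 2-fold and 49 of 50 genes lowered to 0.5-fold met the size rule, and 0 of 7014 unchanged genes did. In cones 35 of 50 and 25 of 50 did, and 0 of 3942 unchanged genes, so a 2-fold change in cones was often missed. Of 100 simulated lists of 20 genes shifted 1.2-fold, 100 stood apart in each class, and of 100 unshifted lists 3 did in rods and 6 in cones.

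Alternatives covered a stricter cell filter, doublets kept, a finer clustering, each library clustered alone, cells thinned to 1000 UMIs, TMM (edgeR 4.0.16 in R 4.3.3) and median-of-ratios scaling, a mean over cells, other pseudocounts, other minimum counts and a total without mitochondrial, ribosomal and rod genes. Thinning left out 7 short-wavelength and 245 white-light rods. Cells with at least 1500 UMIs, and the largest cluster of a class for lists and opsins, were alternatives chosen after seeing the data. RNA velocity, which needs spliced and unspliced counts, was not attempted. A few gene results are not reported here.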

Results

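Single-cell RNA sequencing of mouse retina compared short-wavelength light with full-spectrum white light, with exposure from postnatal day 14 for 2 weeks. The comparison addresses how the spectrum of ambient light affects retinal cells as they mature. Each light condition had 1 library, so there are no replicates, no test was possible, and every difference is a difference between these libraries. All intervals are 95% intervals and cover counting error only. The short-wavelength library held 16106 barcodes with 51681469 unique molecular identifiers (UMIs), a median of 2434 per barcode. The white-light library held 5707 barcodes with 20952589 UMIs, a median of 2784. After filtering, 13764 and 5420 cells were kept.

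Rod-like cells made up most of both libraries, with 92.6% of kept cells (92.2% to 93.1%) under short-wavelength light and 89.6% (88.8% to 90.4%) under white light. With each library clustered alone, the rod shares were 90.4% (89.9% to 90.8%) and 89.8% (89.0% to 90.6%), with intervals that overlapped. Cone-like cells took 3.0% (2.72% to 3.30%) and 3.12% (2.67% to 3.62%). Rod bipolar-like cells took 0.879% (0.730% to 1.05%) and 0.756% (0.543% to 1.02%), and Müller glia-like cells 0.639% (0.513% to 0.787%) and 0.646% (0.450% to 0.897%). Microglia or macrophage-like cells took 0.334% (0.245% to 0.446%) and 0.443% (0.284% to 0.658%). For these classes outside rods, the intervals of the libraries overlapped, so no difference in share was detectable at this depth. Over non-rod cells alone, cones took 40.7% (37.6% to 43.8%) under short-wavelength light and 30.1% (26.4% to 34.1%) under white light, and rod bipolar-like cells 11.9% (9.99% to 14.1%) and 7.31% (5.30% to 9.78%). Unnamed cells took 31.7% and 50.1% of that denominator, which lowers the other white-light shares in it.

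Named inner retinal neurons other than rod bipolar-like cells were few. OFF cone bipolar-like cells numbered 11 under short-wavelength and 5 under white light, and glycinergic amacrine-like cells 10 and 2. Others stayed unnamed because markers of another type scored almost as high. Among them, a cluster with rod and ON cone bipolar markers held 39 and 7 cells, and another with horizontal and ON cone bipolar markers 16 and 7. The finer clustering named an ON cone bipolar-like cluster, whose share is not given here. Erythrocyte-like cells numbered 4 in each library. Unnamed cells took 2.34% (2.09% to 2.61%) under short-wavelength and 5.18% (4.61% to 5.81%) under white light, 2.22-fold lower (1.88 to 2.61) under short-wavelength light, but 1.34-fold lower (1.16 to 1.53) with each library clustered alone. They formed 3 groups. Droplets led by haemoglobin genes beside rod RNA were 0.0218% of the short-wavelength and 1.11% of the white-light library. Droplets with inner retinal RNA were 0.516% and 2.12%. Droplets with RNA of Rlbp1, which encodes a retinaldehyde-binding protein, and of Dapl1 beside rod RNA were 1.80% and 1.96%. Rod RNA was found in the other classes too: Gnat1, the rod transducin gene, stood at 894 and 1228 CPM (UMI counts scaled to a common class total) in cones, at 624 and 692 CPM in Müller glia-like cells and at 750.5 and 989 CPM in microglia or macrophage-like cells.

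**Figure D1:**
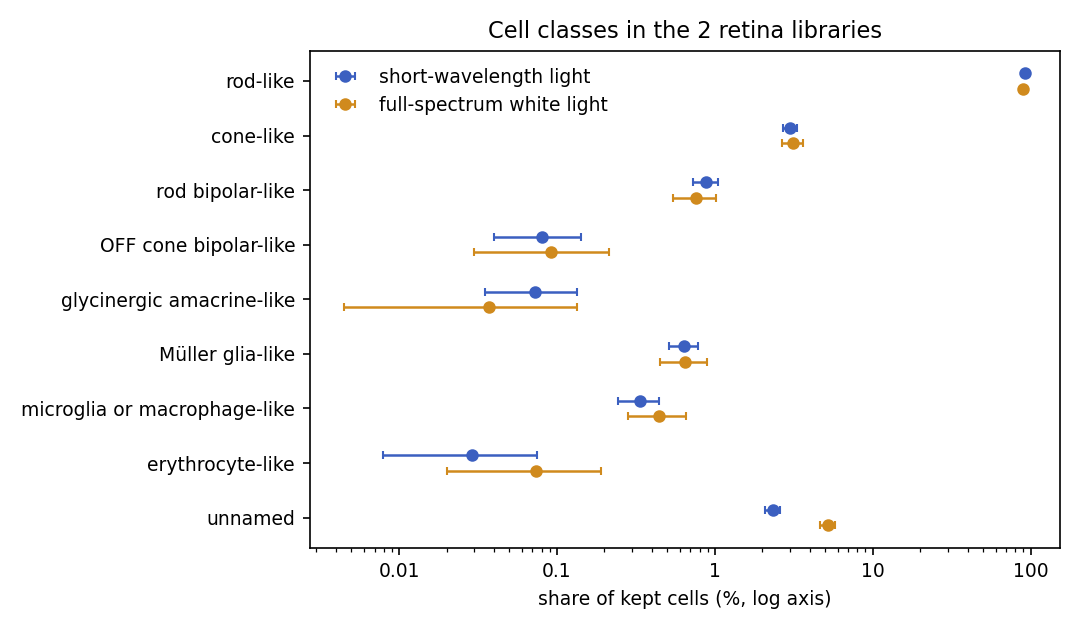
Share of kept cells per class in each library (horizontal log axis, in percent), with points for the 1 library of each light condition and bars for the exact binomial 95% interval. The unnamed class, at 2.34% and 5.18%, has intervals that do not overlap.

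In rod-like cells, Fos, an immediate-early transcription factor gene, was 2.02-fold lower (1.86 to 2.19) under short-wavelength light, at 33.6 CPM against 68.0 CPM under white light. Hbb-bs, a haemoglobin gene that marks RNA from outside rods, differed about as much in rods, at 32.1 CPM against 61.7 CPM. Yet Fos did not follow haemoglobin over the rod clusters. Haemoglobin took 0.00634% of UMIs in rod cluster 9 under short-wavelength light. Under white light it took 0.0185%, the most of the rod clusters. Fos stood there at 12.1 CPM and 11.3 CPM. In the other rod clusters Fos ran from 22.9 to 84.4 CPM under short-wavelength and from 42.2 to 110 CPM under white light. These values argue against free RNA as the whole source of Fos in rods. Fgfbp3, which encodes a binding protein of fibroblast growth factors, was 1.99-fold higher (1.74 to 2.27), at 32.6 CPM against 16.4 CPM. Bc1, a short non-coding RNA of neurons, was 1.91-fold higher (1.71 to 2.12), at 48.6 CPM against 25.5 CPM. In mm10, Fos (ENSMUSG00000021250) lies on chromosome 12 from 85473890 to 85477273, Fgfbp3 (ENSMUSG00000047632) on chromosome 19 from 36917550 to 36919615, and Bc1 (ENSMUSG00000115783) on chromosome 7 from 144914470 to 144914637. Among rod genes of the kinds the naming rule admits, only these had an interval wholly beyond 1.5-fold; the rule leaves out haemoglobin genes and predicted gene models, of which Hbb-bs and Gm48552 were lower in rods and cones. The rod-like cells were spread over several clusters; the most populous was cluster 2 under short-wavelength light and cluster 3 under white light.

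Genes of protein synthesis, respiration and the stress response were lower in short-wavelength rods, each by a small step. All 35 cytosolic ribosomal protein genes were lower, with a median log2 ratio of -0.16, and Rps15 stood at 0.788 times its white-light level (0.759 to 0.818). All 39 nuclear genes of oxidative phosphorylation were lower (median -0.16), with Cox8a at 0.838 times (0.815 to 0.862), and all 13 mitochondrially encoded genes were lower (median -0.21), with mt-Nd2 at 0.780 times (0.758 to 0.803). Of the heat shock and chaperone genes, 12 of 13 were lower (median -0.18), among them Hspa8 at 0.715 times (0.687 to 0.744) and Hspa5 at 0.757 times (0.717 to 0.798). Of the immediate-early genes, 13 of 19 were lower (median -0.13), with Jun at 0.770 times (0.724 to 0.819) and Atf3 at 0.725 times (0.631 to 0.834). Each of these medians lay below all 10000 random lists matched on expression. The antioxidant list (median -0.07, percentile 0.260) lay low, with Gpx1 at 0.820 times (0.711 to 0.948). The outer segment and connecting cilium list (median 0.05, percentile 99.2) lay high, with Rpgr at 1.17 times (1.14 to 1.21). Malat1, a nuclear RNA, was at 56090 CPM in short-wavelength and 50640 CPM in white-light rods. With rods divided into 5 parts by Malat1 share, the median over the parts was 0.0202 for ribosomal and 0.0119 for oxidative phosphorylation genes, but -0.17 for heat shock and -0.16 for immediate-early genes, which were below 0 in every part. Cluster 6 was the largest rod cluster over both libraries. There the ribosomal median was 0.02 and the oxidative phosphorylation median 0.00222, both on the other side of 0. The heat shock (-0.10, percentile 2.58) and antioxidant (-0.03) medians no longer stood apart in cluster 6. Over the 8 rod clusters, the ribosomal median was below 0 in 7 and the oxidative phosphorylation median in 6. The mitochondrial median was below 0 in 5, and ran from -0.39 to 0.13. The heat shock median was below 0 in all 8 and the immediate-early median in 7. With every cell thinned to 1000 UMIs the immediate-early median was -0.03 and no longer stood apart, and the outer segment and antioxidant lists lost theirs too, at 0.03 and -0.04.

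The rod phototransduction list did not stand apart (median -0.04, percentile 8.65), although it did at -0.06 over cells with at least 1500 UMIs. Neither did the rod lists of photoreceptor transcription factors (median -0.01, percentile 57.9), the ribbon synapse (median 0.02, percentile 86.0) or the visual cycle (median 0.02, percentile 84.4). The circadian clock (median -0.04, percentile 6.68), cell death (median -0.04, percentile 6.99) and immature neuron (median -0.04, percentile 16.0) lists stayed within the random range as well. Glycolysis did too (median 0.01, percentile 72.0), but stood apart at 0.11 in the largest rod cluster. Slc16a3, a lactate transporter gene, was at 1.35 times (1.18 to 1.54) and Tpi1 at 1.26 times (1.2 to 1.33), while Ldhb, of lactate dehydrogenase, was at 0.844 times (0.737 to 0.969). The eye growth (median -0.02, percentile 27.6) and dopamine (median -0.02, percentile 36.3) lists showed no shift in rods.

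**Figure D2:**
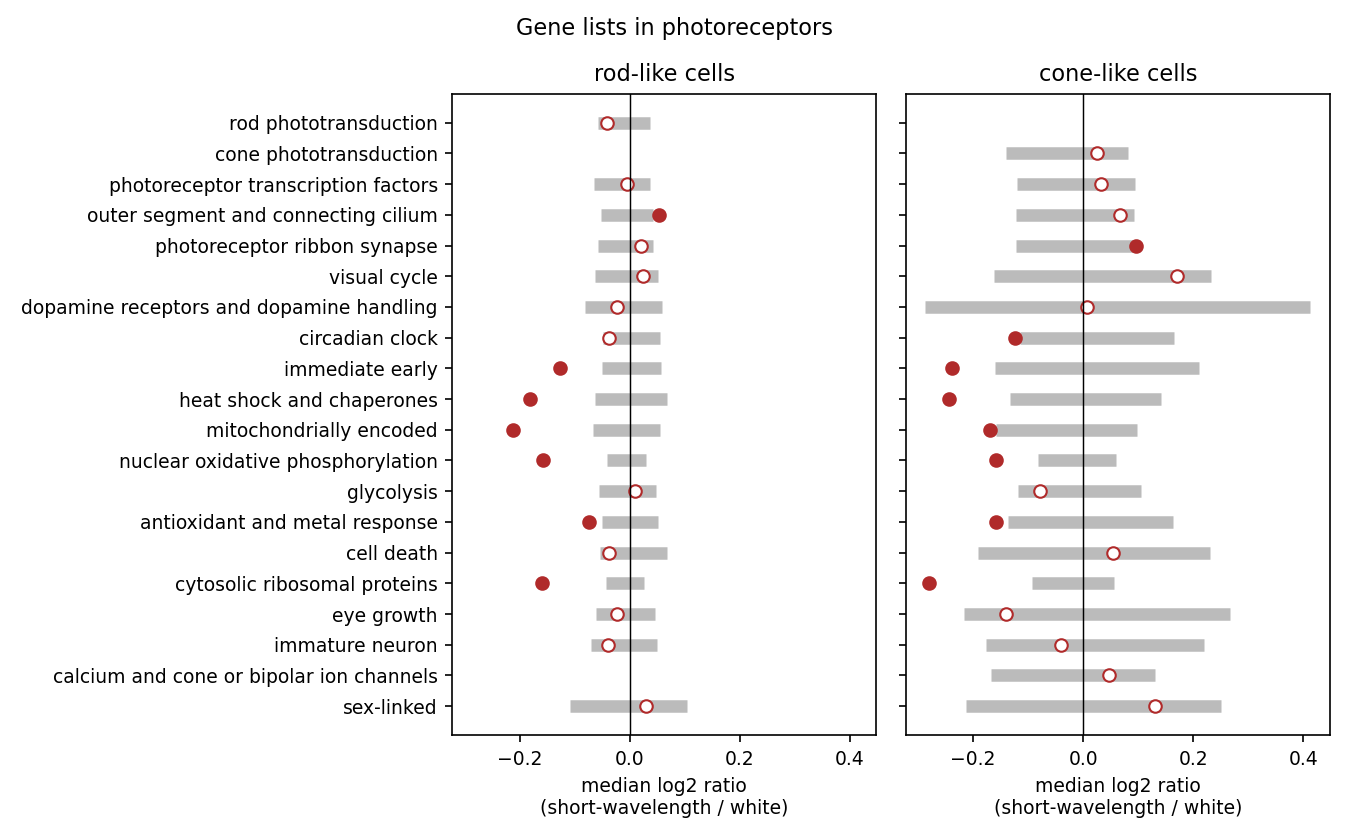
Median log2 ratio of each gene list (horizontal axis, short-wavelength over white light) in rod-like and cone-like cells, with filled points for lists outside the grey bar, which spans the central 95% of 10000 random lists matched on expression. In rods the ribosomal and oxidative phosphorylation lists both sit at -0.16.

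In cone-like cells, Nedd9, a scaffold gene of cell adhesion signalling, was 3.67-fold higher (1.85 to 8.31) under short-wavelength light, at 32.5 CPM against 8.86 CPM. Ndufa9, which encodes a subunit of respiratory complex I, was 2.13-fold lower (1.61 to 2.81), at 44.9 CPM against 95.4 CPM. Hspa8, a chaperone gene, was 1.69-fold lower (1.55 to 1.84), at 515 CPM against 871 CPM. AY036118 was 1.70-fold lower (1.54 to 1.88), but it overlaps other annotated transcripts, so its counts are uncertain. Nedd9 (ENSMUSG00000021365) lies on chromosome 13 from 41309581 to 41487362, Ndufa9 (ENSMUSG00000000399) on chromosome 6 from 126821721 to 126849136, and Hspa8 (ENSMUSG00000015656) on chromosome 9 from 40800984 to 40810087.

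The cone-like cells fell into 2 clusters that the libraries filled differently. Cluster 8 held 338 short-wavelength and 107 white-light cones, and cluster 10, with fewer UMIs per cell, 75 and 62. Malat1 was at 1.17 times its white-light level in cones (1.16 to 1.19), a larger difference than in rods at 1.11 times. Over both clusters, lists lower in rods were lower in cones too. All 35 ribosomal protein genes were lower (median -0.28), with Rplp0 at 0.686 times its white-light level (0.592 to 0.797), as were 36 of 39 oxidative phosphorylation genes (median -0.16), with Atp5b at 0.704 times (0.648 to 0.765). Heat shock and chaperone genes had a median of -0.24, with Hsp90ab1 at 0.667 times (0.594 to 0.750). Immediate-early genes also had a median of -0.24, with Fos at 0.545 times (0.354 to 0.845) and Jund at 0.776 times (0.649 to 0.931). The Fos value rested on 54 and 39 UMIs. Its log2 ratio was 2.14 after thinning, which leaves fewer counts still, so that value is imprecise. All 13 mitochondrially encoded genes were lower (median -0.17), with mt-Nd3 at 0.660 times (0.589 to 0.741). The antioxidant list (median -0.16, percentile 1.22), with Prdx3 at 0.697 times (0.526 to 0.931), and the circadian clock list (median -0.12, percentile 1.78), with Cry1 at 0.696 times (0.509 to 0.959), lay low. The ribbon synapse list lay high (median 0.10, percentile 97.9), with Cacna1f, a calcium channel gene of the photoreceptor terminal, at 1.26 times (1.08 to 1.49). The antioxidant and circadian medians turned to 0.09 and 0.24 after thinning, and the immediate-early, mitochondrial and ribbon synapse lists no longer stood apart there. In cluster 8 alone, the mitochondrial (-0.06), antioxidant (-0.04) and circadian (-0.11) medians did not stand apart. The ribosomal median was -0.11 and the oxidative phosphorylation median -0.08 there, smaller than over both clusters, while heat shock (-0.20) and immediate-early (-0.24) medians moved little.

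Cone phototransduction did not stand apart (median 0.03, percentile 78.8). Nor did the cone lists of transcription factors (median 0.03, percentile 75.8), the outer segment (median 0.07, percentile 92.0), the visual cycle (median 0.17, percentile 89.3), ion channels (median 0.05, percentile 77.9), glycolysis (median -0.08, percentile 9.69) or cell death (median 0.05, percentile 61.5). The eye growth (median -0.14, percentile 8.71), immature neuron (median -0.04, percentile 26.7) and dopamine (median 0.01, percentile 34.0) lists were also within range. Opn1sw, the short-wavelength cone opsin gene, gave 65.8% (65.2% to 66.3%) of Opn1sw and Opn1mw UMIs in short-wavelength cones and 63.9% (63.0% to 64.7%) in white-light cones, a difference of 1.88 percentage points. This balance turned after thinning, to 67.9% and 70.7%, so it has no settled direction.

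The remaining classes had at least 20 cells in each library and were compared after their numbers were seen. In rod bipolar-like cells Bc1 was 3.29-fold higher (2.14 to 5.26) under short-wavelength light, at 230 CPM against 69.9 CPM. Tiam1, which encodes an activator of the GTPase Rac, was 3.0-fold lower (2.04 to 4.44), at 62.1 CPM against 186 CPM. Glycolysis genes lay high (median 0.13, percentile 98.1), with Pgk1 at 1.53 times (1.14 to 2.07). Ribosomal protein genes (median -0.09, percentile 0.860) and eye growth genes (median -0.23, percentile 1.76) lay low, with Igf1, a growth factor gene, at 0.654 times (0.483 to 0.891). The rod bipolar list of ON transduction genes did not stand apart (median 0.02, percentile 61.1), nor did synaptic adhesion and wiring (median 0.02, percentile 61.9). With the mean over cells, the glycolysis (0.15), ribosomal (-0.05) and eye growth (-0.22) medians did not stand apart. After thinning, the immediate-early list of this class, not apart otherwise (median 0.19, percentile 91.2), stood apart at 0.91. Bc1 was thus higher in rods and in rod bipolar-like cells by the same rule.

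In Müller glia-like cells, immediate-early genes were higher under short-wavelength light, the opposite of rods and cones. Fos was 3.61-fold higher (2.70 to 4.92), at 637 CPM against 176 CPM, and Ier2 3.17-fold higher (1.93 to 5.46), at 200.1 CPM against 63.2 CPM. Junb was at 2.01 times (1.34 to 3.1) and Egr1 at 1.92 times (1.26 to 3.01), and 11 of 13 measured members of the list were higher (median 0.78, percentile 100). Heat shock genes had a median of 0.39 (percentile 99.8), with Hsp90ab1 at 1.68 times (1.16 to 2.48) but Hspa8 at 0.587 times (0.386 to 0.894). Fos UMIs were found in 44.3% of short-wavelength and 48.6% of white-light Müller glia-like cells, at median depths of 5784 and 8013 UMIs, against 7.37% and 15% of rods at 2316 and 2730, where Hbb-bs UMIs were found in 8.64% and 18.8%. After thinning, the immediate-early median was 0.09 and the heat shock median 0.18, and neither stood apart. With doublets kept, the Fos log2 ratio was 0.82 in place of 1.82. Without the 5 short-wavelength and 2 white-light cells with the most Fos, its ratio was 2.29 (1.59 to 3.39).

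Ctnna3, which encodes an alpha-catenin, was 14.3-fold higher in Müller glia-like cells (4.73 to 71.1) on 78 and 3 UMIs. Qrfpr, a neuropeptide receptor gene, was 3.01-fold higher (1.57 to 6.35) and Slc25a3, the mitochondrial phosphate carrier gene, 2.38-fold higher (1.54 to 3.80). Tafa1 was 2.75-fold lower (1.92 to 3.98) and Mbd1 2.91-fold lower (1.85 to 4.64), the latter on 33 and 53 UMIs. After thinning, which leaves fewer counts, Mbd1 turned to a log2 ratio of 1.69 and Qrfpr was at 0.25. Glial homeostasis genes lay high (median 0.15, percentile 99.9), with Spc25 at 1.34 times (1.19 to 1.52), as did Notch pathway genes (median 0.29, percentile 98.7), with Hes1 at 1.29 times (1.06 to 1.57). The reactive state list (median 0.20, percentile 90.3) and the angiogenesis list (median 0.02, percentile 58.6) did not stand apart. Sex-linked genes lay low in Müller glia-like cells (median -0.46, percentile 0.830, 4 genes). With the mean over cells, the homeostasis (0.06), Notch (0.18), heat shock (0.10) and sex-linked (-0.33) medians no longer stood apart.

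**Figure D3:**
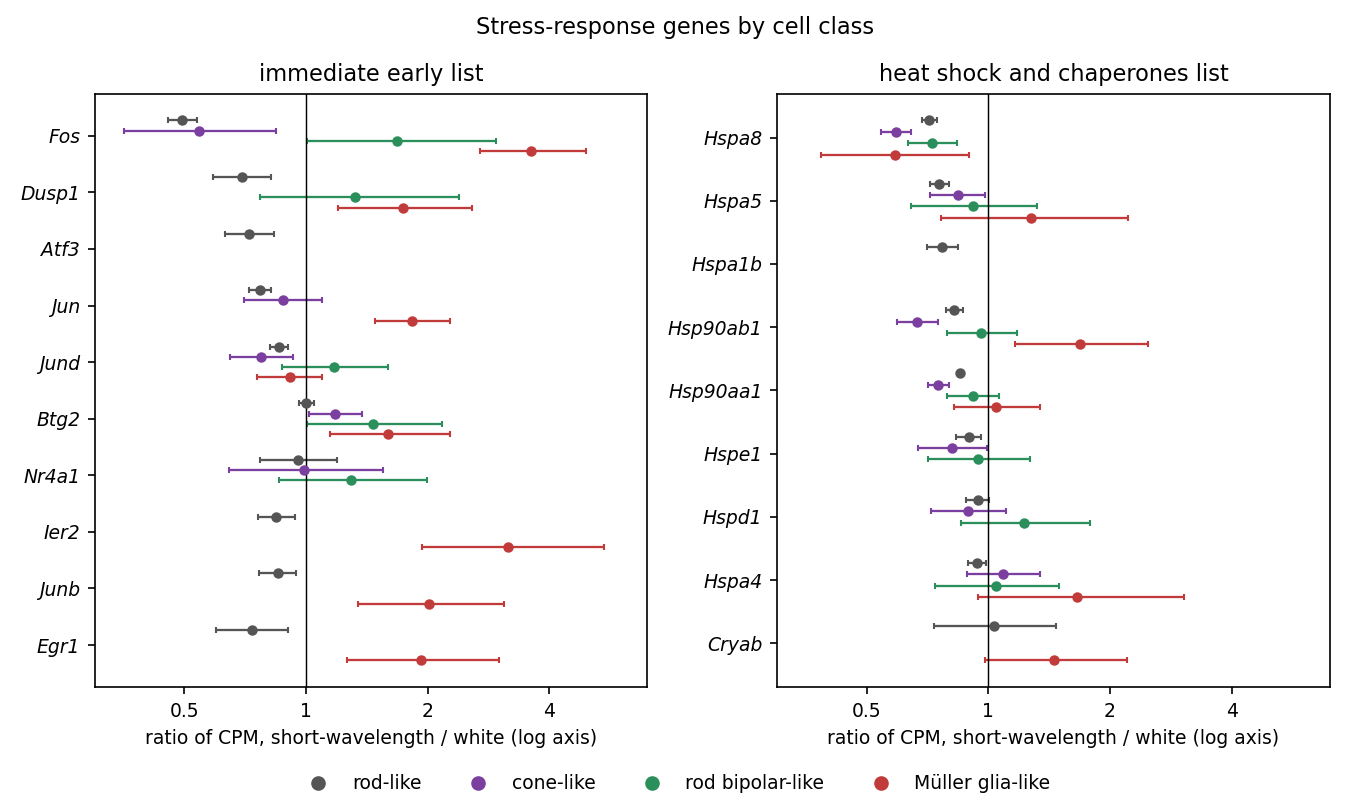
Ratio of CPM, short-wavelength over white light (horizontal log axis), of immediate-early and heat shock genes in 4 cell classes, with points for summed counts of 1 library per condition and bars for the 95% counting interval. Fos lies at 0.494 in rod-like and 3.61 in Müller glia-like cells.

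In microglia or macrophage-like cells, all 11 microglial homeostasis genes were higher under short-wavelength light (median 0.58, percentile 99.99), with Tmem119 at 1.92 times (1.48 to 2.51) and Siglech at 1.75 times (1.34 to 2.31). Egr3 was 5.76-fold higher (2.49 to 16.3), Rgs1 3.84-fold (2.02 to 8.05), Pde4b 3.46-fold (1.81 to 7.29), Rgs2 2.62-fold (1.78 to 3.98) and Mt1, a metallothionein gene, 2.43-fold (1.76 to 3.41). Among activation genes, Tnf was at 2.00 times (1.32 to 3.12) and Ccl4 at 1.72 times (1.48 to 2.00), while Cd74, of antigen presentation, was 2.27-fold lower (1.58 to 3.29); that list did not stand apart (median 0.37, percentile 97.1), but did at 0.84 after thinning. The homeostasis median no longer stood apart after thinning (0.38) or with the mean over cells (0.33). Cd74 leads the smaller cluster of this class, and in the larger cluster alone its log2 ratio was 0.10. These 46 and 24 cells carried less rod RNA under short-wavelength light, with Sag at 1020 CPM against 2473 CPM. After thinning, Rgs2 turned to a log2 ratio of -0.30 and Mt1 was at 0.38.

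Of 44 ligand and receptor pairs, 25 had both partners expressed in these classes. Psap, the prosaposin gene, was at 1.73 times its white-light level (1.44 to 2.09) in microglia or macrophage-like cells, beside its receptor gene Gpr37 at 1.04 times (0.868 to 1.26) in Müller glia-like cells. Igf1 in rod bipolar-like cells was at 0.654 times (0.483 to 0.891), beside Igf1r at 1.04 times (0.873 to 1.25) in Müller glia-like cells. The Csf1 value beside its receptor gene Csf1r rested on 6 and 6 UMIs in microglia or macrophage-like cells, too few to read.

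Over all kept cells, Th, the gene of dopamine synthesis, had 1 UMI under short-wavelength and 0 under white light, and Vip 0 and 1. Opn3 had 9 and 5 UMIs, Opn5 4 and 7, and Opn4, the melanopsin gene, 6 and 0; a count of 0 allows up to 0.156 CPM in the white-light library. The Y-linked genes Ddx3y (98.9 and 99.1 CPM) and Eif2s3y (197.8 and 193.0 CPM) were at like levels in both libraries, and Xist had 7 and 0 UMIs. Crystallins and non-visual opsins had too few measured members for a list value.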

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

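The test of a shared dissociation response was chosen only after the result was seen, as was the comparison of Müller glia-like cells itself. The same contrast went in opposite directions in photoreceptors and Müller glia-like cells, and these differences between cell classes were not tested.

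Fos differed between rods and Müller glia-like cells by -2.74 on the log2 scale, from -0.92 in rods to 1.82 in Müller glia-like cells. The immediate-early list differed by -0.91 between rods and Müller glia-like cells and by -1.02 between cones and Müller glia-like cells. The heat shock list differed by -0.57 between rods and Müller glia-like cells and by -0.63 between cones and Müller glia-like cells.

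For the immediate-early difference, microglial RNA in the Müller glia-like droplets is argued against by the summed microglia markers there, at a ratio of 0.909 (0.481 to 1.77). A few Müller glia-like cells with very high Fos are argued against as the whole cause. Without the 5% of cells with the most Fos in each library, the ratio was still 2.29 (1.59 to 3.39). Fos UMIs in the short-wavelength library dropped from 347 to 146, however. The Fos ratio was also smaller with doublets kept, over 95 and 38 cells in place of 88 and 35. A few cells thus bear on its size. One dissociation response shared by all cell types cannot be told apart. Outside rods and Müller glia-like cells, Fos was at a ratio of 0.944 (0.848 to 1.05) in microglia or macrophage-like and 1.68 (1.01 to 2.95) in rod bipolar-like cells. In cones it was at 0.545 (0.354 to 0.845), below 1 as in rods, which goes against a shared direction. The cone value rested on 54 and 39 UMIs, however, and went the other way after thinning. A response that differs by cell type and an effect of the light itself were not tested and stay open. Free RNA is argued against as the whole source of Fos in rods. Under white light Fos was at 11.3 CPM in rod cluster 9, which had the most haemoglobin, and at 42.2 to 110 CPM in the others. C1qa, a microglia marker, was at 1.83 and 1.52 CPM in rods. In microglia or macrophage-like cells it was at 3572 and 2744 CPM, beside Fos at 2841 and 3010 CPM. Whether free RNA adds a part was not tested. After thinning to 1000 UMIs the Müller glia-like list median was 0.09. Thinning left 87 and 35 cells of 1000 UMIs each, from sums of 544628 and 300593 UMIs. It therefore cannot tell an effect of depth from a loss of counts, and a part played by depth stays open.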

How the results depend on the processing

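No paired analysis was possible because each group has 1 library. The alternatives with at least 1500 UMIs per cell, and the largest cluster alone for lists and opsins, were chosen after seeing the data. Of 285 genes, 139 stayed within their counting interval under all alternatives run, as did 6 of 9 shares; 4 of the 15 lists that stood apart in rods or cones did so under all of theirs. TMM and median-of-ratios factors shifted the median of all genes by at most 0.04 log2. Except where stated, the causes of the changes were not tested.

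With non-rod cells as denominator, the log2 ratio of shares was 0.43 for cones and -0.66 for unnamed cells. Unnamed cells moved to -0.42 with each library clustered alone and to -0.90 over cells with at least 1500 UMIs. With doublets kept, the erythrocyte ratio was -4.41, since that clustering named 4 short-wavelength and 30 white-light droplets so. The cone opsin difference was 0.752 points with doublets kept, 3.93 in the largest cone cluster and reversed to -2.78 after thinning.

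After thinning to 1000 UMIs, the rod medians were 0.0344 (outer segment), -0.0292 (immediate-early) and -0.040 (antioxidant), and the cone medians 0.12 (ribbon synapse), -0.15 (immediate-early) and -0.12 (mitochondrial). The cone circadian (0.24) and antioxidant (0.0854) medians were reversed there. In the largest cluster alone, rod oxidative phosphorylation (0.00222) and ribosomal (0.0183) medians were reversed, and those of heat shock (-0.10) and antioxidant genes (-0.0258) in rods and of circadian (-0.11), mitochondrial (-0.0587) and antioxidant genes (-0.0429) in cones no longer stood apart.

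The other cone lists that no longer stood apart were these. With the mean over cells: ribbon synapse (0.0756), circadian (-0.15), immediate-early (-0.16) and mitochondrial (-0.15). With at least 1500 UMIs: ribbon synapse (0.0863), circadian (-0.11) and antioxidant (-0.14). With each library alone: circadian (-0.11) and antioxidant (-0.12). The circadian median was -0.10 with members of at least 50 UMIs and -0.10 with no minimum. The mitochondrial median was -0.14 with the stricter cell filter and -0.11 with doublets kept, and the antioxidant median -0.11 at the finer resolution.

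Among named genes, Cd74 in microglia or macrophage-like cells was reversed (0.10) in the larger cluster, which leaves out the cluster Cd74 leads. Mbd1 in Müller glia-like cells (1.69) and Rgs2 in microglia or macrophage-like cells (-0.30) were reversed after thinning, which leaves fewer counts per gene and so less precise values. The few cells, 88 and 35 Müller glia-like and 46 and 24 microglia or macrophage-like, limit the precision in these classes.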

Other observations

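The tests of depth, of rod clusters, of the mitochondrial part and of doublets were chosen only after the results were seen. The test by rod cluster first used the largest cluster alone and was widened to all clusters once their values were known.

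A rod-like cluster with Edn2, an endothelin gene, and Cebpd, a transcription factor gene, among its 10 leading genes held 2.15% (1.91% to 2.41%) of short-wavelength and 2.05% (1.69% to 2.46%) of white-light cells. Stmn1 in rods, a gene of immature neurons, was at 0.663 times its white-light level (0.544 to 0.809).

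Ribosomal protein and respiratory chain RNA was lower in short-wavelength rods. A difference in depth is argued against as the whole cause by rods of 2000 to 3000 UMIs, where the ribosomal median was -0.0918, below all random lists. A different share of nuclear RNA per droplet stays open: with rods divided into 5 parts by Malat1 share, the median ribosomal value was 0.0202, from -0.08 to 0.12 over the parts, so the loss may reflect droplets with more nuclear RNA. For the mitochondrially encoded part the parts gave -0.0942, from -0.28 to 0.26, and this cannot be told apart from a loss of its own because the parts go both ways. A different mix of rod clusters also stays open, at a median of -0.0597 over 8 clusters (from -0.12 to 0.02), as these genes lead some of those clusters; an effect of light was not tested.

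In the white-light library, 146 unnamed droplets carried rod RNA with haemoglobin or inner retinal RNA, against 8 in the short-wavelength library. The inner retinal droplets among them came from clusters picked because white-light droplets far outnumbered short-wavelength ones there. That part of the contrast was thus fixed by the choice. The haemoglobin droplets, 60 white-light and 3 short-wavelength, were not picked by number. Left out were, among others, a further inner retinal cluster (0.203% of white-light and 0.0509% of short-wavelength cells) and the Rlbp1 and Dapl1 droplets (1.96% and 1.80%). Doublets of whole cells are argued against for most of the 146 droplets by their median of 1889 UMIs, 0.692 times that of white-light rods. By cluster, this median ran from 0.444 to 1.07 times that of white-light rods. Free RNA and debris of other cells caught with a rod were not tested and stay open, as does an effect of light.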
